A study of Mus musculus with 80 samples.

How the data were processed

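Gene expression was measured on Affymetrix arrays in subcutaneous white adipose tissue of male mice of the BXD family and of both parental strains. Per the labels' protocols, total RNA was extracted from each animal, the RNA of about 5 animals of 1 strain and 1 diet was pooled in equal amounts, and each pool was amplified, labelled and hybridized to 1 array. The mice were 29 weeks old and fasted overnight, and those on high fat had been on that diet from week 8. There were 80 arrays, 42 on chow and 38 on high fat. No hybridization date or array batch is given for them.

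Per the labels, the arrays were processed with Affymetrix Expression Console and RMA, without versions. The values deposited by the authors are a score. Each of the 80 arrays had a mean of 8 and a standard deviation of 2 over its 65770 features, which RMA output alone would not have, so log-scale values were rescaled within each array at a step that is not described. A scale unit is therefore 0.5 of an array's SD, not a log2 unit, and no fold changes are given. A rescaling of this kind sets the mean of every array equal, so a change of one gene is relative to all other features. The annotated table and the values of the series record held the same numbers (0 values differed), so only the annotated table was used. The design had assumed log2 values and a 1.5-fold change as a second threshold. After the unit was seen, a mean change of at least 0.5 scale units took its place.

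Features without a gene symbol (26355) were set aside, and the feature with the highest mean over all arrays stood for each symbol, which left 38827 genes, with no filter on low values. Gene symbols are as deposited, and 32388 of them were found, as current symbols or synonyms, in a gene table of the GRCm38.p6 assembly, which served for names only. Some symbols are older ones, such as Emr1 for Adgre1, Prkcdbp for Cavin3 and Atp5g1 for Atp5mc1.

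The diet effect was tested in the 38 strains with 1 array on each diet (76 arrays), with strain as a fixed block, by limma's moderated test with Benjamini-Hochberg adjustment and a threshold of 0.05. The pairing comes from the strain label. Strains were the replicates, so p-values measure the spread between pools of different strains, and a strain-specific response counts as spread. The 4 strains on chow alone entered only 1 alternative. Strain effects were tested in the same fit with limma's moderated F test over the 37 strain coefficients, and the share of variance between strains was the intraclass correlation after the diet means were removed. The parents were compared by a contrast of their strain coefficients in that fit. Each parent had 2 arrays, 1 per diet, and the residual spread came from all 38 strains.

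Before the data were examined, 36 gene lists with 679 members were fixed, and 674 members were matched (not Tm7sf2, Hbb-b1, Hbb-b2, Hba-a1 and Ahsp). The lists were tested with limma's camera (preset inter-gene correlation 0.01, two-sided), camera with an estimated correlation, and fry. A sign-flip permutation test of each list's mean change over the 38 strains (100000 resamples, two-sided) was added after the data were seen. Lists share some members, such as Lep, Lcn2, Egr2, Cpt1b, Dld, Cat, Hk2, Per1 and Slc2a4, and several marker genes are also expressed by fat cells.

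Strain labels were checked between diets. For each of the 36 BXD strains, the chow array was correlated with every high fat array over the 200 genes with the largest parental difference of the same sign in both diets. A strain matched when its own high fat array correlated best, and the count was compared with 100000 permutations. After the result was seen, the check was repeated over the 100 genes whose levels fell most clearly into 2 clusters of at least 8 strains, in all 38 strains. No array was moved to another strain or diet.

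Changes (high fat minus chow) of each list's mean, with Lep left out of the lists, were correlated with the change of Lep across the 38 strains by Pearson's r and Spearman's rho, with two-sided permutation tests (100000 resamples, so that 1e-05 is the smallest p they can give), adjusted over the 36 lists, and again without the 2 strains whose Lep change was farthest from the median. The same correlation for each of 38826 genes was added after the data were seen.

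Genes to name were fixed before the data were examined. For diet they were the 10 genes with the largest and the 10 with the most negative mean change among those past the threshold and changed in 1 direction in at least 30 strains, a fixed set (Lep, Mest, Sfrp5, Npr3, Adipoq, Pparg, Fasn, Scd1, Ucp1, Emr1, Itgax, Trem2, Ccl2, Slc2a4 and Bckdha), and the 3 members with the largest change of each list that was called or had at least 0.25 of its members past the threshold. For strain, they were the 10 genes with the largest share of variance, and for the parents the 5 largest differences in each direction. Predicted and clone models (16973 symbols) were counted and not named, and a few genes that the rule names are not reported here.

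The steps were tested on simulated data of the same layout with 38827 genes. For the diet contrast, 58 of 67 genes changed by 0.25 units were called (86.6%), 66 of 67 changed by 0.5 units (98.5%) and 66 of 66 changed by 1 unit, with 12 calls among 38627 unchanged genes. For the strain effect, 191 of 200 genes with a strain SD of 1.5 residual SD were called (95.5%), with 5 calls among the others. None of 36 unchanged lists was called, and the parents' contrast gave 0 calls among 38627 genes without a simulated difference. The simulated noise was independent between genes and of equal spread on every array. False calls from correlated genes or odd arrays, which matter for the lists and the parents, could therefore not appear. The simulated data went through the main fit alone, not through alternatives such as robust regression. With diet assigned at random within strains in the real data, camera called a median of 12 lists.

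The alternatives fixed before the data were examined were quantile normalization of the deposited scores, equal array medians, a filter that left out the lowest 40% of genes, the mean of a gene's features, BXD strains alone, limma array weights, the means of the B cell, skeletal muscle and skin lists as covariates, robust regression, a fit without the strain block, all 80 arrays with strain as a random block, the Wilcoxon signed-rank test, every feature as its own test, and each strain left out in turn. Added later were fits on the 23 strains with matching arrays, without C57BL/6J and BXD63, on protein-coding genes alone, and with 3 principal components of olfactory and vomeronasal receptor genes as covariates. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.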

Results

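Subcutaneous white fat was profiled in 42 strains of male mice: 40 BXD strains, which are inbred lines derived from a cross of C57BL/6J and DBA/2J, and both parents. Of the 80 arrays, 42 came from mice on chow and 38 from mice fed a high fat diet from week 8 to week 29. Each array held 1 pool of about 5 animals, killed at 29 weeks after a fast from 6 pm to 9 am. In 38 strains (36 BXD strains and the 2 parents) 1 pool of each diet was measured. BXD56, BXD60, BXD92a and BXD96 were measured on chow alone. Levels are deposited scores with a mean of 8 and an SD of 2 on every array, so differences are given in scale units of 0.5 array SD and not as folds. Values are means ± SD over the 38 strains unless stated otherwise, and adjusted p-values are limma's. They measure the spread between pools of different strains. No strain had a second pool on the same diet, and the number of arrays limits the precision.

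The comparison of diets within strains asks which transcripts of this fat depot differ after prolonged high fat feeding in genetically different mice. On high fat, 15 of 19 macrophage markers, 9 of 10 markers of fat cell expansion, 26 of 32 matrix genes, 21 of 22 cell cycle genes and 17 of 21 cholesterol synthesis genes were higher, and 15 of 18 skeletal muscle, 11 of 18 B cell and 9 of 19 T cell markers were lower. As lists these passed camera with its preset correlation and none passed with an estimated one (adjusted p = 0.747 for each). Among named genes past the threshold and higher in at least 30 strains, Lipf, a lipase, had the largest increase, 2.01 ± 1.68 units. It was higher in 35 of 38 strains (adjusted p = 1.75e-08). Atp6v0d2, a subunit of the vacuolar proton pump found in macrophages, was higher by 1.79 ± 1.55 units in 33 strains and Tm4sf19, a tetraspan membrane protein, by 1.78 ± 1.10 in 37. Cd68, a lysosomal protein of macrophages, went from 10.9 ± 0.66 to 12.1 ± 0.71 (higher in 37 strains, adjusted p = 3.23e-10), and Il1rn, the interleukin-1 receptor antagonist, rose by 1.25 ± 0.80. Ubd, a ubiquitin-like protein, rose by 1.47 ± 1.16, Paqr9 by 1.32 ± 1.25, Cdkl4 by 1.31 ± 1.21 and the pseudogene Mup-ps21 by 1.30 ± 0.83. The microRNA gene Mir200c was higher in all 38 strains, by 1.80 ± 0.31 units (adjusted p = 3.78e-28).

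Lower on high fat were Cyp2e1, a cytochrome P450 that oxidizes ethanol and ketones, which fell by 2.14 units (SD 1.45, lower in 37 strains, adjusted p = 1.67e-10), and Cyp2f2, another cytochrome P450, which fell by 1.61 (SD 1.02, lower in 35). Cfd, the fat cell protease adipsin, went from 15.1 ± 0.49 to 13.9 ± 0.68 and was lower in 35 strains (adjusted p = 6.12e-13). Acsm3, an acyl-CoA synthetase, changed by -1.35 ± 1.12 units and Thrsp, a regulator of lipogenesis, by -1.18 ± 1.21. The 5 remaining genes of the 10 largest decreases shared by at least 30 strains are expressed in striated muscle, and their SDs exceeded their means: Myh4, a fast myosin heavy chain (-1.47 ± 3.07, lower in 30 strains, adjusted p = 0.00745), Trdn (-1.41 ± 2.31), Txlnb (-1.20 ± 1.68), Klhl41 (-1.20 ± 1.99) and Actn3 (-1.16 ± 2.38).

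In all, 23752 of 38827 genes (61.2%) changed with diet, 14257 higher and 9495 lower. Most changes were small. The median absolute change of these genes was 0.165 units, 701 genes changed by at least 0.5 units (379 higher, 322 lower), and 26 were higher and 24 lower by at least 1 unit. Olfactory and vomeronasal receptor genes, which adipose tissue is not known to use, were called about as often as all genes (1083 of 1766, 61.3%, 515 higher and 568 lower). The median absolute change of the called receptor genes was 0.187 units, above the 0.165 of all called genes, and 11 of them changed by at least 0.5 units.

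**Figure D1:**
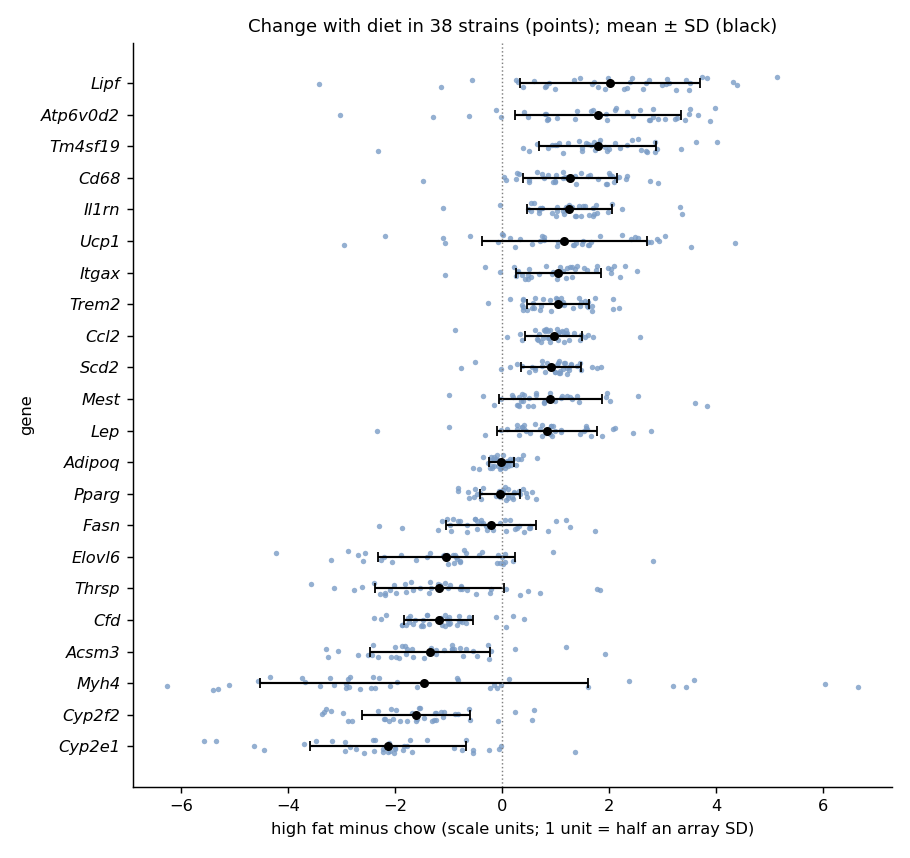
Change with diet (high fat minus chow, in scale units) of 22 genes, with 1 blue point per strain and the mean ± SD of the 38 strains in black. Cyp2e1 is lower in 37 strains, Cd68 is higher in 37, and Myh4 varies between strains by more than its mean change.

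Macrophage genes rose. Of the 19 macrophage markers, 15 were higher and 1 lower, and the list's mean rose from 10.3 ± 0.31 to 10.7 ± 0.36, higher in 35 strains (camera adjusted p = 0.000993). Emr1, which encodes the macrophage surface protein F4/80, was higher by 0.98 ± 0.85 units and Ms4a7 by 0.83 ± 0.72. Markers of lipid-associated macrophages, a state described in the fat of obese animals, rose by 0.72 ± 0.55 units as a list, with 12 of 15 members higher and 1 lower (higher in 35 strains, camera adjusted p = 0.000347). Trem2, the lipid-sensing receptor of these cells, was higher by 1.04 ± 0.59 in 37 strains, Itgax (CD11c) by 1.05 ± 0.79 and Mmp12, a metalloelastase, by 1.17 in 29. Among 23 chemokines and inflammatory mediators, 16 were higher and 2 lower, and the list rose in 36 strains (0.35 ± 0.23 units, camera adjusted p = 0.00510). Ccl2, which attracts monocytes, was higher by 0.96 ± 0.53 in 37 strains and Ccl9 by 0.95 ± 0.89. Interferon response genes rose less, with 14 of 23 higher and 0 lower (0.16 ± 0.27 units, camera adjusted p = 0.0283). Rsad2 was higher by 0.48 ± 0.52, Ifi44 by 0.37 ± 0.50 and Oasl2 by 0.35 ± 0.42. Each of these 4 lists had an adjusted p = 0.747 with an estimated correlation. The interferon list also lost its call after quantile normalization (adjusted p = 0.05002), without the lowest 40% of genes (adjusted p = 0.0876), with the B cell, muscle and skin lists as covariates for tissue mix (adjusted p = 0.341) and without BXD83 (adjusted p = 0.0512). It lost it too by robust regression (adjusted p = 0.115), without the strain block (0.0716), with all 80 arrays (0.132) and without C57BL/6J and BXD63 (0.0526).

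Genes that follow fat cell growth rose as well. Of 10 expansion markers, 9 were higher and 0 lower (list mean 0.49 ± 0.57 units, higher in 35 strains, camera adjusted p = 0.0271, and adjusted p = 0.747 with an estimated correlation). Lep, the hormone leptin, was higher by 0.83 ± 0.93 in 34 strains, from 13.7 ± 0.75 to 14.5 ± 0.56 (adjusted p = 4.64e-06). Mest, an imprinted marker of fat mass gain, was higher by 0.90 ± 0.96, Peg3 by 0.66 ± 1.01, Sfrp5 by 0.58 ± 0.87 and Npr3, the natriuretic peptide clearance receptor, by 0.42 ± 0.63. With the tissue covariates Npr3 no longer passed (0.24, adjusted p = 0.0663), nor did the expansion list (adjusted p = 0.231, and 0.0684 with all 80 arrays).

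The fat cell identity genes did not move as 1 group. Of 17, 2 were higher and 6 lower, with a list mean of -0.09 ± 0.22 (camera adjusted p = 0.161, sign-flip adjusted p = 0.0194). Adipoq, the hormone adiponectin, differed by -0.02 ± 0.23 units (adjusted p = 0.697), Pparg, the master regulator of fat cells, by -0.05 ± 0.37 (adjusted p = 0.510) and Slc2a4, the insulin-responsive glucose transporter, by -0.05 ± 0.35 (adjusted p = 0.444). The difference of Adipoq was 0.02 after quantile normalization, that of Pparg was -0.22 and past the threshold with the tissue covariates (adjusted p = 0.00101), and that of Slc2a4 was -0.12 and past it after quantile normalization (adjusted p = 0.0439). Adrb3, the adrenergic receptor that drives lipolysis, was lower by a mean change of -0.87 ± 0.90.

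Lipid synthesis genes went both ways. Of 22 genes of fatty acid and triglyceride synthesis, 7 were higher and 6 lower (-0.06 ± 0.42 units, camera adjusted p = 0.560, sign-flip adjusted p = 0.455). Elovl6, a fatty acid elongase, changed by -1.04 ± 1.27 and Scd2, a desaturase, by 0.91 ± 0.56, higher in 35 strains. Fasn, fatty acid synthase, differed by -0.22 ± 0.84 (adjusted p = 0.148, and 0.0294 by robust regression). Scd1, the main desaturase of fat cells, was lower in 28 strains (-0.14 ± 0.18, adjusted p = 0.000108), but its difference was 0.06 and not past the threshold after quantile normalization (adjusted p = 0.203). Cholesterol synthesis genes rose together, with 17 of 21 higher and 0 lower (0.30 ± 0.32 units, higher in 33 strains, camera adjusted p = 0.00128, and adjusted p = 0.747 with an estimated correlation). Nsdhl was higher by 0.77 ± 0.62, Hsd17b7 by 0.56 ± 0.42 and Lss, lanosterol synthase, by 0.56 ± 0.48.

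In mitochondria, genes of fatty acid oxidation rose. Of 19 beta-oxidation genes, 12 were higher and 0 lower (0.19 ± 0.22 units, higher in 32 strains, camera adjusted p = 0.0134, and adjusted p = 0.747 with an estimated correlation). Cpt1a, which commits fatty acids to mitochondrial import, was higher by 0.54 ± 0.38 in 35 strains, Hadhb by 0.39 ± 0.36 and Acadm by 0.39 ± 0.29. With the tissue covariates the list no longer passed (adjusted p = 0.221), nor with all 80 arrays (adjusted p = 0.0767). Oxidative phosphorylation had 24 of 50 genes higher and 7 lower (0.08 ± 0.15 units), led by Ndufb3 (0.82 ± 0.45), Atp5g1 (-0.52 ± 0.32) and Atp5g3 (0.33 ± 0.19), with a camera adjusted p = 0.177. The tricarboxylic acid cycle had 9 of 17 higher and 1 lower (0.09 ± 0.23, camera adjusted p = 0.350), with Idh3a at 0.28 ± 0.44, Dlat at 0.23 ± 0.38 and Cs, citrate synthase, at 0.22 ± 0.30. Of 31 genes of the mitochondrial ribosome, 17 were higher and 2 lower (0.08 ± 0.11, camera adjusted p = 0.0817), with Mrpl16 at 0.27 ± 0.26, Mrps28 at 0.25 ± 0.18 and Mrpl13 at 0.25 ± 0.19. Among 15 mitochondrial chaperones and proteases 7 were higher and 0 lower (0.09 ± 0.11, camera adjusted p = 0.127), among them Htra2 (0.31 ± 0.18), Atf5 (0.30 ± 0.24) and Lonp1 (0.17 ± 0.15). Peroxisome genes had 9 of 22 higher and 1 lower (0.08 ± 0.16, camera adjusted p = 0.213), with Hsd17b4 at 0.37 ± 0.37 and Acaa1a at 0.26 ± 0.20. These 5 lists passed the sign-flip test of their own mean (adjusted p = 0.00609 for oxidative phosphorylation, 0.0384 for the tricarboxylic acid cycle, 0.000231 for the ribosome, 0.000166 for the chaperones and 0.00609 for the peroxisome), and did not pass camera, which compares a list with all other genes. The sign-flip test compares a mean with 0, and 28 of the 36 lists passed it. Over all genes the median change was 0.027 units and 61.2% changed with diet, so these lists are not set apart from other genes.

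Thermogenic genes were split. Ucp1, the uncoupling protein of brown and beige fat cells, was higher by 1.16 ± 1.54 units in 31 strains (adjusted p = 6.85e-05), Otop1 by 0.88 ± 0.68 and Elovl3 by 0.73 ± 0.67, and in all 8 of 16 were higher and 3 lower (0.21 ± 0.31, camera adjusted p = 0.325, sign-flip adjusted p = 0.000408). Branched-chain amino acid catabolism had 5 of 22 higher and 5 lower (-0.01 ± 0.18, camera adjusted p = 0.584). Bckdha, of the rate-limiting dehydrogenase complex, differed by 0.04 ± 0.21 (adjusted p = 0.354), by -0.03 after quantile normalization, and by 0.05 with a robust fit, which called it (adjusted p = 0.0241). Aldh6a1 was lower in 30 strains (-0.32 ± 0.33) and Ppm1k in 35 (-0.27 ± 0.22), and Bckdhb was higher in 31 (0.24 ± 0.44) but not past the threshold with the tissue covariates (adjusted p = 0.394). Insulin signalling had 6 of 19 higher and 3 lower (0.03 ± 0.15, camera adjusted p = 0.911, with its mean above 0 and its camera direction lower), with Grb14, an inhibitor of the insulin receptor, at 0.53 ± 0.63, Pde3b at -0.29 ± 0.42 and Irs3 at 0.28 ± 0.31.

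The matrix and vessel genes rose. Of 32 collagens and matrix genes, 26 were higher and 1 lower (0.34 ± 0.33 units, higher in 33 strains, camera adjusted p = 0.000137). Thbs1, thrombospondin 1, was higher by 1.23 ± 1.30, Postn, periostin, by 0.74 ± 0.60 and Tnc, tenascin C, by 0.54 ± 0.53. Endothelial markers rose by 0.22 ± 0.26 units (12 of 16 higher, 0 lower, higher in 30 strains, camera adjusted p = 0.00437), with Tie1 at 0.44 ± 0.29, Cldn5 at 0.42 ± 0.41 and Esam at 0.37 ± 0.32. With the tissue covariates the endothelial list rose by 0.12 and did not pass (adjusted p = 0.199). The cell cycle list had the smallest camera p of the 36 lists (adjusted p = 1.39e-08). Of its 22 genes 21 were higher and 0 lower (0.32 ± 0.20 units, higher in 35 strains). Mki67, a marker of cycling cells, was higher by 0.55 ± 0.50, and Bub1 (0.53 ± 0.25) and Ccnb1 (0.51 ± 0.23) were higher in all 38 strains, at low levels of 6.76 and 7.53 on high fat. The matrix, endothelial and cell cycle lists each had an adjusted p = 0.747 with an estimated correlation. Fibroblast and progenitor markers had 4 of 16 higher and 4 lower (0.04 ± 0.21, camera adjusted p = 0.911, camera direction lower), with Lum at 0.51 ± 0.60, Pdgfrb at 0.37 ± 0.34 and Dpp4 at -0.33 ± 0.59. Smooth muscle and pericyte markers had 7 of 12 higher and 1 lower (0.11 ± 0.20, camera adjusted p = 0.188). Acta2 was higher by 0.75 ± 0.84 and Cspg4 by 0.30 ± 0.21, and Des, which skeletal muscle also expresses, changed by -0.69 ± 1.40 and not past the threshold with the tissue covariates (adjusted p = 0.614).

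Among stress and hormone responses, immediate-early genes rose (13 of 19 higher, 1 lower, 0.22 ± 0.16 units, higher in 34 strains, camera adjusted p = 0.0199). Atf3 was higher by 0.88 ± 0.52, Egr2 by 0.61 ± 0.25 and Dusp1 by 0.50 ± 0.52. Endoplasmic reticulum stress genes rose by 0.11 ± 0.11 units (12 of 19 higher, 0 lower, higher in 32 strains, camera adjusted p = 0.0271), with Dnajb9 at 0.26 ± 0.28, Sdf2l1 at 0.25 ± 0.20 and the chaperone Hspa5 at 0.22 ± 0.27. Both lists had an adjusted p = 0.747 with an estimated correlation, and the stress list lost its call after quantile normalization (adjusted p = 0.154), without the lowest 40% of genes (adjusted p = 0.0547) and with the tissue covariates (adjusted p = 0.302). By robust regression neither list passed (adjusted p = 0.0694 for immediate-early genes and 0.0782 for stress genes), nor did the stress list with all 80 arrays (0.0968). Hypoxia genes had 7 of 16 higher and 2 lower (0.09 ± 0.10, camera adjusted p = 0.434, sign-flip adjusted p = 6.55e-05), with Adm at 0.61 ± 0.65, Hif1a at 0.27 ± 0.31 and P4ha1 at 0.24 ± 0.18. Antioxidant genes were 7 higher and 7 lower of 21 (-0.02 ± 0.15, camera adjusted p = 0.647), with Hmox1, heme oxygenase, at 0.63 ± 0.49, Gsta4 at -0.68 ± 0.56 and Gpx3 at -0.55 ± 0.48. Glucocorticoid response genes were 5 higher and 2 lower of 12 (0.06 ± 0.26, camera adjusted p = 0.824), with Lcn2, lipocalin 2, at 0.61 ± 0.52, Mt1 at -0.34 ± 0.38 and Zbtb16 at -0.31 ± 0.41. Clock genes were 4 higher and 4 lower of 17 (-0.01 ± 0.13, camera adjusted p = 0.697), with Nfil3 at 0.19 ± 0.25 and Bhlhe41 at 0.19 ± 0.27.

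Markers of skeletal muscle and of B and T cells fell and varied widely between arrays, and the source of these transcripts was not tested. Skeletal muscle markers fell by 0.92 units with an SD over strains of 2.10 (15 of 18 lower, 0 higher, lower in 27 strains, camera adjusted p = 0.00289), and single arrays ranged from 8.89 to 14.2 in the mean of the list. Ttn, titin, changed by -1.45 (lower in 28 strains) and Neb, nebulin, by -1.41 ± 2.87. B cell and lymph node markers changed by -0.39 ± 0.90 (11 of 18 lower, 1 higher, lower in 23 strains, camera adjusted p = 0.0121), with Cxcl13, a lymphoid chemokine, at -0.84 ± 1.42, Cr2 at -0.83 ± 1.35 and Ms4a1 (CD20) at -0.77 (lower in 25 strains). T cell and natural killer markers changed by -0.21 ± 0.46 (9 of 19 lower, 1 higher, lower in 25 strains, camera adjusted p = 0.0199), with Cd3e at -0.61 ± 1.00 and Cd8b1 at -0.59 ± 0.69. Each of these 3 lists had an adjusted p = 0.747 with an estimated correlation. With the tissue covariates the T cell list changed by -0.03 and lost its call (adjusted p = 0.302). Without the strain block it lost the call with an unchanged -0.21 (adjusted p = 0.0513). By robust regression neither the B cell list (adjusted p = 0.0757) nor the T cell list (0.0782) passed, and with all 80 arrays the T cell list did not (0.0684).

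**Figure D2:**
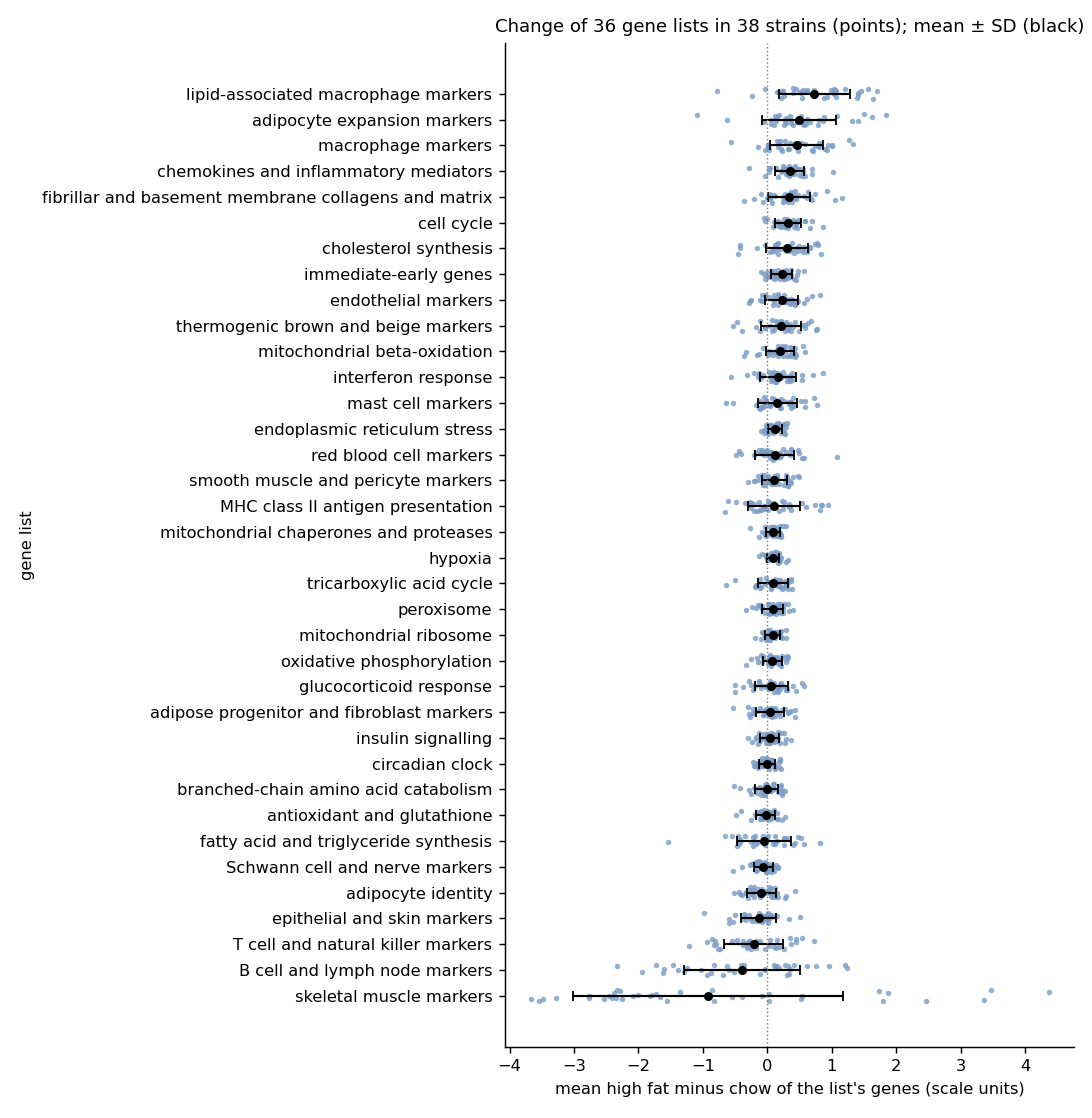
Change with diet (high fat minus chow, in scale units) of the mean of each of the 36 gene lists, with 1 blue point per strain and the mean ± SD of the 38 strains in black. The lipid-associated macrophage list is higher in 35 strains, and the skeletal muscle list is lower in 27 strains and higher in 11.

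The remaining cell type lists were not called by camera, although the skin (adjusted p = 0.00558), mast cell (0.00609), Schwann cell (0.0127) and red blood cell (0.0315) lists passed the sign-flip test. Skin and epithelial markers had 8 of 16 lower and 1 higher (-0.14 ± 0.27, camera adjusted p = 0.0542), with Krt10 at -0.48 ± 0.79, Dsp at -0.37 ± 0.71 and Krt5 at -0.36 ± 0.64. Schwann cell markers had 8 of 14 lower and 2 higher (-0.06 ± 0.14, camera adjusted p = 0.0817). Mast cell markers had 6 of 10 higher and 0 lower (0.15 ± 0.31, camera adjusted p = 0.146), with Tpsb2 at 0.33 ± 0.44, Hdc at 0.32 ± 0.23 and Kit at 0.24 ± 0.31. Of 8 genes of MHC class II presentation 1 was higher, Ctss, a protease (0.66 ± 0.65), and 1 lower, H2-Aa (-0.26 ± 0.54), with a list mean of 0.10 ± 0.40 (camera adjusted p = 0.821). Red blood cell markers had 5 of 8 higher and 0 lower (0.11 ± 0.30, camera adjusted p = 0.211), with Alas2 at 0.15 ± 0.35.

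Camera with the preset correlation called 15 of the 36 lists, 12 higher and 3 lower, and camera with an estimated correlation called 0 (smallest unadjusted p = 0.0634, for the cell cycle list). Fry, which tests whether a list's genes move on balance 1 way, called 27 (22 higher, 5 lower), and the sign-flip test of each list's mean passed 28 (22 higher, 6 lower). In 40 of 100 random assignments of diet within strains, the real one included, camera called at least 15 lists, so the number of calls does not by itself separate the diets. The strain counts and SDs above include 15 strains whose arrays did not match by label, and they show little for the B cell, T cell and muscle lists, whose SDs far exceed their means. Adjusted over the list alone, 12 B cell genes were lower, 4 branched-chain genes lower, 22 cell cycle genes higher, 18 cholesterol genes higher, 3 clock genes lower, 27 matrix genes higher, 16 macrophage genes higher, 13 beta-oxidation genes higher, 6 mitochondrial chaperones higher and 16 muscle genes lower. The counts of all other lists were equal to those over all genes tested.

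The F test over the 38 strains asks which levels differ between strains beyond the spread left after diet, and called 4035 genes (10.4%). Serpina1b, an alpha-1-antitrypsin paralog, ranged from 8.97 to 13.8 between strain means, with 0.766 of its variance between strains. Stab2, a scavenger receptor, ranged from 8.08 to 11.3 (share 0.753), Mrap2, a melanocortin receptor accessory protein, from 8.00 to 9.99 (share 0.744), Zfp949, a zinc finger gene, from 9.16 to 11.1 (share 0.818) and Igh-V11, an immunoglobulin segment, from 7.41 to 9.15 (share 0.773). Over the 38 strains by label, the largest share of a named gene was that of Stard6 (0.849). Comp (0.773), Atp10d (0.761), Nlrp1b, an inflammasome sensor (0.734), and Mapre3 (0.728) completed the 10 largest. In these data 226 genes had a share of at least 0.6, and the median share of all genes was 0.146. These shares and strain means combine arrays by label, and 15 of the 38 strains had arrays that did not match. Of the strain genes, 2480 also changed with diet, where 2468 would if both were independent. The count depended on the fit and on C57BL/6J. It was 2656 without C57BL/6J and 1949 without both parents, 7974 with array weights and 33816 by robust regression.

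Arrays of the same strain on each diet did not always resemble each other. Over the 200 genes with the largest difference between the parents, the chow array of 20 of the 36 BXD strains correlated best with the high fat array of its own strain label (permutation p = 1e-05, the smallest the permutations can give, and at most 7 by chance). With 100 genes the count was 20 and with 500 it was 18. Over 100 genes whose levels fell into 2 clusters of strains, chosen after that result, 23 of 38 strains matched, with r between 0.776 and 0.963 across genes, which are not independent replicates. In the other 15 strains the r between the arrays of the label was between -0.296 and 0.311. For 14 of these, the chow array and a high fat array under another label picked each other, with r between 0.801 and 0.922. Chow BXD51 paired with high fat BXD55 (0.816) and chow BXD55 with high fat BXD51 (0.912). Along the run of labels from BXD73 to BXD95, chow BXD79 paired with high fat BXD73, BXD80 with BXD75, BXD81 with BXD79, BXD83 with BXD80, BXD84 with BXD81, BXD85 with BXD83, BXD87 with BXD84, BXD89 with BXD85, BXD90 with BXD87, BXD95 with BXD89, BXD73 with BXD90 and BXD75 with BXD95. The chow array labelled BXD63 had no such partner (best r 0.369), and the high fat array labelled BXD63 resembled chow BXD43 (0.816).

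**Figure D3:**
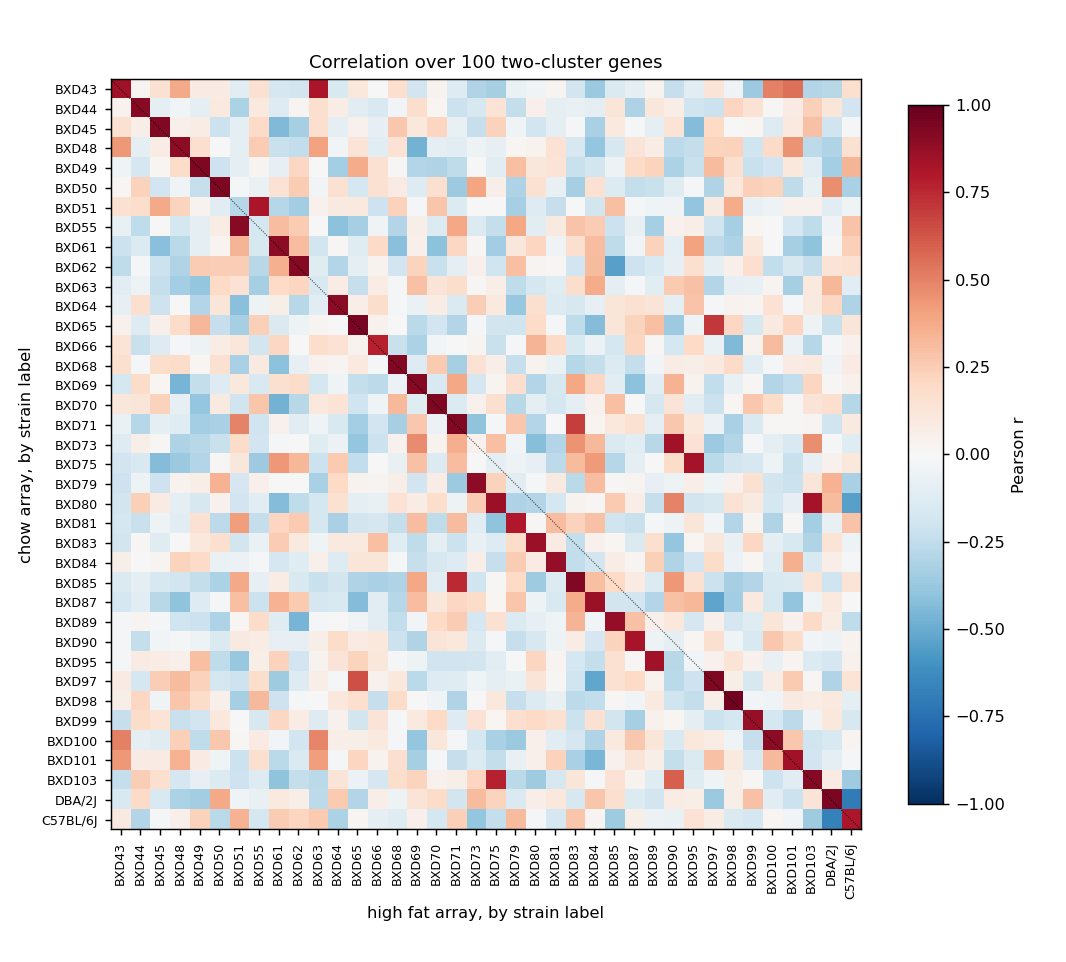
Pearson r, over the 100 genes whose levels fall into 2 clusters, of each chow array (vertical axis) with each high fat array (horizontal axis), both ordered by strain label, with the diagonal dotted. In 23 strains the highest r of the chow array lies on the diagonal, and for the chow labels BXD79 to BXD95 it lies to the left of it.

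In the 23 strains whose arrays matched, 6759 genes besides the 100 of the match had a strain effect. These strains were chosen because their arrays agreed, which favours a higher count and higher shares. The median share of all genes was 0.190 there, against 0.146 in the 38 strains. The share was 0.976 for Serpina1b, 0.970 for Zfp949, 0.937 for Stab2, 0.937 for Mrap2 and 0.878 for Stard6. Of these, Stab2 alone was not among the 100 genes of the match. Diet changed 21225 genes in the 23 strains, and 19855 of them were among those of the 38 strains with the same direction. Camera called 22 lists there, among them the 15 of all strains. The 23 strains are part of the 38, so the same arrays enter both fits and the overlap of genes and lists is not independent evidence.

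The contrast of the parents asks which genes differ between the strains that carry the alleles segregating in the BXD family. Among the largest differences, Ucp1 and Serpina1b were higher in DBA/2J and 5 immunoglobulin segments in C57BL/6J. Ucp1 was at 11.6 on chow and 13.4 on high fat in DBA/2J and at 6.96 and 7.11 in C57BL/6J, a difference (C57BL/6J minus DBA/2J) of -5.46 units (SE 1.04, adjusted p = 0.000965). Serpina1b differed by -4.20 (SE 0.90) and Serpina1c by -3.12 (SE 0.68), although the mean of all Serpina1c features differed by -1.03 and did not pass (adjusted p = 0.0830). Tmem45a differed by -3.03 (SE 0.81). Higher in C57BL/6J were Ighv1-53 (4.04, SE 0.91), Ighv1-76 (3.79, SE 0.92), Igh-VJ558 (3.76, SE 0.87), Ighv1-80 (3.53, SE 0.69) and a segment of the kappa light chain (3.43, SE 0.79). The B cell and lymph node list was at 11.1 in C57BL/6J and 9.59 in DBA/2J (10.4 on chow and 8.78 on high fat), and its BXD mean was 10.3 ± 0.65 (SD, n = 36 strains).

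**Figure D4:**
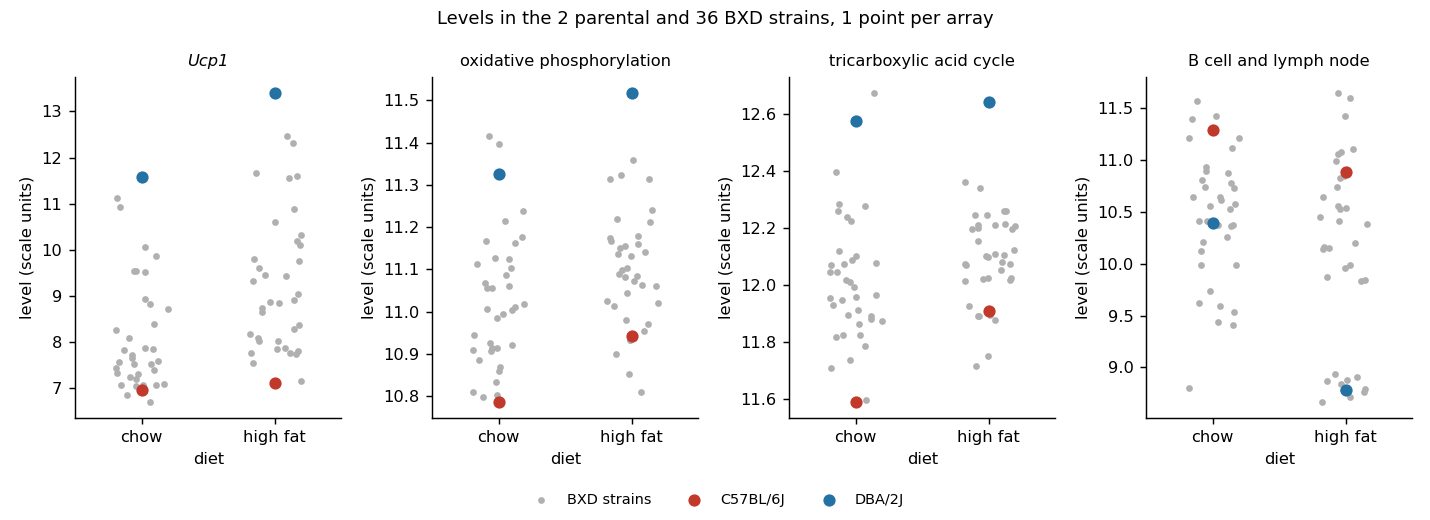
Levels (scale units) of Ucp1 and of the means of the oxidative phosphorylation, tricarboxylic acid cycle and B cell lists by diet, with 1 point per array, grey for the 36 BXD strains, red for C57BL/6J and blue for DBA/2J. Ucp1 is at 11.6 and 13.4 in DBA/2J and at 6.96 and 7.11 in C57BL/6J.

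In all, 4539 genes differed between the parents, 1791 higher in C57BL/6J and 2748 higher in DBA/2J, and 892 by at least 1 unit (736 higher in C57BL/6J). The count rests on C57BL/6J as much as on the contrast. In the same fit C57BL/6J differed from a BXD strain in a median of 1564 genes (207 to 7241 over the 36 strains), and DBA/2J in a median of 22 (0 to 2174). With array weights, which gave the C57BL/6J arrays a weight of 0.275, 6 genes differed and none of the genes named for this contrast passed (adjusted p = 0.101 for Ucp1), and with the tissue covariates 1962 differed, with Ighv1-76 not past the threshold (adjusted p = 0.0630). By robust regression, whose false calls were not checked on simulated data, 13234 differed. Features were not checked for sequence differences between the strains. A difference in hybridization is therefore not separated from one in expression, here, in the strain effects or in the genes with 2 clusters.

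The last comparison asks which gene groups changed with Lep from strain to strain, since Lep transcript tracks fat cell size and strains differ in weight gain. Lep also varied within each diet. On chow it ranged from 12.2 (BXD55, change 2.77) to 14.9 (BXD69, change -0.325). On high fat it ranged from 11.6 (BXD63, change -2.34) to 15.1 (BXD66, change 0.403). Both changes of a strain come from the same 2 arrays. Covariation of levels between pools of 1 diet therefore enters r, and is not separated from a shared response. The change of Lep ranged from -2.34 to 2.77 units over the 38 strains. Expansion markers other than Lep rose most where Lep rose most (r = 0.84, permutation p = 1e-05, the smallest possible, rho = 0.758, p = 1e-05), and r was 0.79 without the 2 strains farthest from the median. The collagen and matrix list followed Lep with r = 0.75 (p = 1e-05, adjusted p = 0.00018, rho = 0.666, p = 3e-05, 0.65 without the 2 strains), and cholesterol synthesis with r = 0.60 (p = 5e-05, adjusted p = 0.0006, rho = 0.565, p = 0.00029, 0.53 without them). Chemokines had r = 0.48 (p = 0.00294, adjusted p = 0.0132, rho = 0.392, p = 0.0155, 0.47 without them), and did not pass by rho (adjusted p = 0.0698). T cell markers went the other way, with r = -0.50 (p = 0.00116, adjusted p = 0.00786, rho = -0.452, p = 0.00518), and r = -0.42 without the 2 strains (adjusted p = 0.0719).

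**Figure D5:**
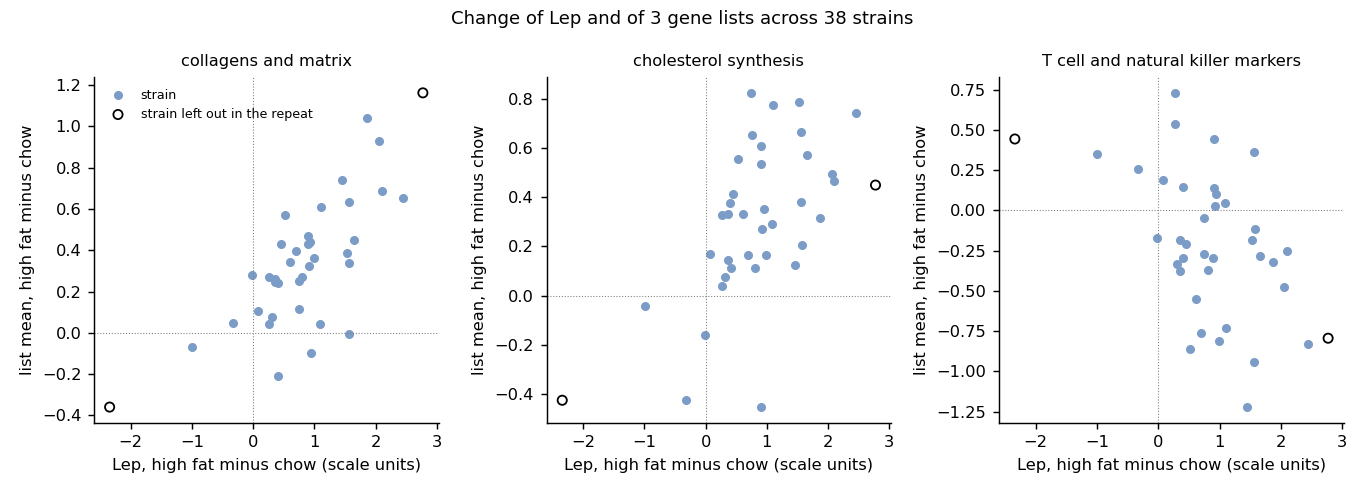
Change of the mean of the matrix, cholesterol synthesis and T cell lists against the change of Lep (both high fat minus chow, in scale units), with 1 point per strain for 38 strains and open circles for the 2 strains farthest from the median. The matrix list (r = 0.75) rises with Lep and the T cell list (r = -0.50) falls.

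In all, 17 of the 36 lists passed, 14 positive and 3 negative. Besides those above they were endoplasmic reticulum stress (r = 0.52, p = 0.00062, rho = 0.473, p = 0.00314, 0.40 without the 2 strains), macrophages (r = 0.50, p = 0.00131, rho = 0.357, p = 0.0287, 0.37 without them), antioxidant genes (r = 0.50, p = 0.00222, rho = 0.258, p = 0.116, 0.31 without them) and lipid-associated macrophages (r = 0.46, p = 0.00373, rho = 0.427, p = 0.00794, 0.39 without them). The red blood cell, branched-chain, beta-oxidation, endothelial, peroxisome and cell cycle lists passed in the positive direction and the Schwann cell and B cell lists in the negative one, with adjusted p between 0.0340 and 0.0468, and of these 8 the Schwann cell list alone also passed by rho (adjusted p = 0.0311). The macrophage (adjusted p = 0.0862) and antioxidant (0.190) lists did not pass by rho either. Without BXD55 and BXD63, the 2 strains farthest from the median, only the expansion, matrix, cholesterol and chemokine lists passed. The other 13 no longer did, although r changed little in some (-0.41 to -0.40 for the Schwann cell list) and more in others, such as the antioxidant list. Both are among the 15 strains whose arrays did not match by label. In BXD strains alone 11 lists passed, in the 23 strains with matching arrays 8, with the 3 tissue lists regressed out 4 of the 33 others, over levels within high fat 5, and over levels within chow 13 (11 positive, 2 negative, 9 of them among the 17).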

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

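The parents' diet response and that of all pairs of strains, the repeated label check and most tests of the patterns here were chosen after the results were seen, and the test of tissue mix, the correlation of the chow arrays labelled BXD73 and BXD103 and the random assignments of diet were set before.

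In a test of the difference between the parents' diet responses, 646 genes passed (6730 at an unadjusted p under 0.05). With 1 array per parent and diet, a difference between the strains is not separated from a single odd pool. Of all 703 pairs of strains 22 gave as many genes, 16 of them with C57BL/6J, which differed from a BXD strain in a median of 456 genes, and DBA/2J in a median of 0. The largest were immunoglobulin segments that were higher on high fat in C57BL/6J and not in DBA/2J, such as Igh-V7183 (3.73 against -0.30 units, adjusted p = 0.00818) and Igh-V10 (3.18 against 0.03). Chrdl1, an antagonist of bone morphogenetic proteins, changed by 1.39 in C57BL/6J and by -1.05 in DBA/2J (adjusted p = 0.0448), and the microRNA gene Mir5115 by -2.00 and -0.01. Of 26355 features without a gene symbol, 15545 changed with diet (59.0%, 6553 higher and 8992 lower), a share no higher than that of the receptor genes (61.3%), and 511 of these changed by at least 0.5 units.

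In 15 strains the arrays of both diets did not match over genes with 2 clusters of levels, and weak strain signal or noisy arrays as the cause are argued against by the unmatched chow arrays' best r, with a median of 0.854. An exchange of high fat strain labels may account for 14 of the 15, whose chow arrays had a high fat array under another label that picked them back with r above 0.7. BXD103 and BXD80 are known as substrains of the BXD73 line, and r = 0.822 (SE 0.035 over genes) between their chow arrays argues against an exchanged chow label of BXD80, while chow BXD73 and BXD80 had 0.373, no more than the upper bound of 0.376 on most pairs of different labels. An exchange of chow labels along the run from BXD73 to BXD95, with the high fat labels right, is argued against by r = -0.378 (SE 0.092) between the high fat arrays labelled BXD80 and BXD103 (0.157 for BXD73 and BXD103, -0.026 for BXD73 and BXD80), where high fat BXD75 and BXD90, the partners of chow BXD80 and BXD73, had 0.775 and 0.608 with BXD103. For BXD51, BXD55 and single labels of the run other than BXD80 an exchange on the chow side cannot be told apart. Except for BXD73, they have no substrain here. The chow arrays labelled BXD73 and BXD103 had r = 0.523 (SE 0.079), above the bound of 0.5 set beforehand. That r lies within 2 SE of the bound, a margin that was not part of the bound as set, so BXD73 was left undecided.

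Diet changed 23752 genes, most of them by little, and chance is excluded for this count, which 1 of 100 assignments of diet within strains reached (the real one, with 2045 as the highest of the others). A different content of lymph node, muscle and skin as the whole cause is argued against by 19585 genes changed with those lists as covariates. Of these, 18046 were shared with the same direction. Other cell types, such as macrophages, were not covariates, so a different mix of them stays open. The rescaling of each array is argued against for the receptor genes alone, which lie in a narrow range of levels (47.6% of those changed were higher). It stays open for genes at other levels. Of the changed genes, 67.2% were higher without the lowest 40% of genes, and 51.9% after quantile normalization. An array-wide difference between the diets' arrays, in hybridization, array batch or RNA quality, could account for many of the small changes, since 61.3% of receptor genes changed too. With 3 components of the receptor genes as covariates 24229 genes changed (23679 of them shared with the same direction), but the diet means were removed before the components were taken, so a difference that follows diet stays in that fit. A broad response of the tissue to diet stays open and untested. Changes of at least 0.5 units were rare among receptor genes (11 of 1766, against 701 of 38827). The median absolute change of called receptor genes, 0.187 units, was nevertheless above the 0.165 of all called genes.

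Skeletal muscle markers were lower on high fat in 27 strains. A larger share of fat cells as the only change in cell mix would lower every other cell type. The endothelial list argues against that, with a rise of 0.222 units (SD 0.256), or 0.120 with the tissue covariates (camera adjusted p = 0.199). Macrophage (0.456), mast cell (0.155), red blood cell (0.111) and smooth muscle (0.108) markers rose too. B cell (-0.389), T cell (-0.208), skin (-0.135) and Schwann cell (-0.064) markers fell, so a larger share next to other changes stays open. The fat cell identity list itself did not rise. It changed by -0.092 units (SD 0.219, lower in 23 strains, camera adjusted p = 0.161, sign-flip adjusted p = 0.0194). A varying amount of muscle taken with the fat pad remains a candidate explanation. The changes of the muscle list's 18 members moved together across strains (mean pairwise r 0.925), and the muscle list ranged from 8.89 to 14.2 between arrays. A diet effect in muscle present in every pool cannot be told apart from it, because the list was higher on high fat in 11 strains, but only in 5 of the 23 whose arrays matched by label, too few to decide.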

How the results depend on the processing

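The fits on 23 matching strains, without C57BL/6J and BXD63, on protein-coding genes alone and with receptor components were chosen after the data were seen, and the causes were not tested unless fewer or more genes or strains explain a count. Changed genes stayed between 19585 and 28982 in every fit of the 38827 genes. They were 14062 without the lowest 40% of genes, 13154 for protein-coding genes alone (452 of them by at least 0.5 units) and 39453 for every feature (1224 by at least 0.5 units), all of which change the number tested, and the share of higher genes was 51.9% after quantile normalization. Without the strain block, the pairing of the diets, 22536 genes and 13 lists passed, and it changed no other count by over 1.5 times. Tissue covariates gave 400 genes of at least 0.5 units, 8 of 33 lists and 1962 genes for the parents, whose count was 6 with array weights and 13234 by robust regression. Lists called were 0 with an estimated correlation and 27 by fry. Strain genes were 1949 without the parents, 7974 with array weights, 33816 by robust regression, 6759 in 23 strains, and 2656 (without C57BL/6J) to 4699 (without BXD51) with each strain left out. Lists that followed Lep were 11 in BXD strains, 4 of 33 with tissue regressed out, 13 within chow, 5 within high fat and 8 in 23 strains. Of the changes of named genes under all these settings, 2389 kept direction and side of the threshold, 32 kept direction and lost the call and 13 gained one. No reversed change was past the threshold, and of these genes only Scd1 had been before. They were, after quantile normalization, Adipoq 0.024, Scd1 0.056, Bckdha -0.033, Comp -0.0063, Atp10d -0.016 and Nlrp1b 0.00092, with array weights Ighv1-76 -0.032, with tissue covariates Ighv1-53 0.35, Igh-VJ558 0.24, Ighv1-80 0.11 and a kappa light chain segment 0.20, by robust regression Serpina1b -0.013, Stab2 0.014 and Ighv1-76 -0.031, with 80 arrays Serpina1b -0.0068, by Wilcoxon Serpina1b 0 and Stab2 0.014, in 23 strains Pparg 0.013, Serpina1b -0.064, Stab2 0.00039, Nlrp1b 0.019 and Ighv1-76 -0.095, and without C57BL/6J and BXD63 Stab2 0.028 and Ighv1-76 -0.016. With each strain left out in turn, Serpina1b ranged from -0.081 to 0.12, Stab2 from -0.057 to 0.036, Nlrp1b from -0.019 to 0.00024 and Ighv1-76 from -0.12 to 0.10. The series values equal the annotated ones and gave no other value. Genes near the floor of the arrays, such as the receptors, limit what signal over background can show.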

Other observations

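The tests of the parents' gene lists, of each parent against the BXD strains, of all pairs of strains, of single genes against Lep and of the gap in the B cell list were chosen after results were seen, and the random assignments and exchanged strains were set before.

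DBA/2J had the highest mean of 38 strains in the mitochondrial lists and in several lists of fat cells. Of 50 oxidative phosphorylation genes 37 were higher in DBA/2J than in C57BL/6J and 0 lower (list difference, C57BL/6J minus DBA/2J, -0.56 units, camera adjusted p = 1.42e-21), of 17 tricarboxylic acid cycle genes 16 (-0.86) and of 19 beta-oxidation genes 16 (-0.90). Among 16 thermogenic genes 7 were higher in DBA/2J (-1.29), Ucp1 (-5.46), Otop1 (-2.33) and Elovl3 (-1.82) among them, and in branched-chain amino acid catabolism 9 of 22 (-0.49), with Bckdhb at -1.68. It ranked highest in the oxidative phosphorylation, tricarboxylic acid cycle, beta-oxidation, mitochondrial ribosome and chaperone, peroxisome, thermogenic and branched-chain lists, and also in the fat cell identity (-0.37, camera adjusted p = 0.00320), fatty acid synthesis (-0.66), cholesterol synthesis, insulin signalling and hypoxia lists. C57BL/6J had the lowest mean in the beta-oxidation, thermogenic and mitochondrial chaperone lists, but also in the matrix, endothelial, smooth muscle, expansion, antioxidant, hypoxia, clock, glucocorticoid, immediate-early and chemokine lists, so its arrays stand apart beyond mitochondrial genes. In oxidative phosphorylation it ranked 4 from the lowest (10.9 against 11.4 in DBA/2J and 11.1 ± 0.12 in 36 BXD strains). MHC class II genes (4 of 8) and T cell genes (4 of 19) were higher in C57BL/6J (0.87 and 0.91 units, camera adjusted p = 1.08e-05 and 1.37e-07). The B cell and lymph node list differed by more (1.5 units, camera adjusted p = 9.15e-08, with 0 of 18 genes past the threshold), and the high fat array of DBA/2J is among the 12 arrays with the lowest level of that list, so the lymph node content of the pools is not separated from the strain. With an estimated correlation none of these lists passed (smallest adjusted p = 0.0869), and each parent had 2 arrays. With array weights 6 of 38827 genes differed between the parents, so the counts of member genes above do not hold in that fit.

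The largest r of a single gene with Lep was above that of any list, but it is the best of 38826 genes against the best of 36 lists. In 15 of the 38 strains the arrays did not match by label, and the genes were not tested again without these. The change of 6062 of 38826 genes correlated with that of Lep across the 38 strains, 4027 positively and 2035 negatively. Lpgat1, a lysophospholipid acyltransferase, had r = 0.942 (permutation p = 1e-05, the smallest they can give, adjusted p = 0.000395, rho = 0.926, p = 1e-05, and 0.921 without the 2 farthest strains). Lbp, the lipopolysaccharide binding protein, had r = 0.934 (p = 1e-05, rho = 0.937, p = 1e-05, 0.920 without them), and Cav1, the caveolar protein that fat cells carry at high level, r = 0.921 (p = 1e-05, rho = 0.906, p = 1e-05, 0.880 without them). The caveolar gene Prkcdbp had r = 0.926 (p = 1e-05, rho = 0.891, p = 1e-05, 0.883 without them) and Anxa2, an annexin, r = 0.930 (p = 1e-05, rho = 0.860, p = 1e-05, 0.907 without them). Several genes of RNA splicing went the other way. Rsrp1 had r = -0.841 (p = 1e-05, rho = -0.796, p = 1e-05, -0.850 without them), Safb2 r = -0.812 (p = 1e-05, rho = -0.733, p = 1e-05, -0.770 without them) and Clk2, a kinase of splicing factors, r = -0.759 (p = 1e-05, rho = -0.721, p = 1e-05, -0.752 without them). These genes were picked for their r, and no splicing list was tested.

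The B cell and lymph node list fell into separate clusters. Of the 80 arrays, 12 lay at or below 8.93 and the others at or above 9.41. On chow 1 array (BXD73, 8.80) lay in the lower cluster and 41 in the upper, and on high fat 11 and 27 (Fisher's exact test, two-sided, p = 0.00107). The 11 were labelled BXD44, BXD55, BXD65, BXD66, BXD70, BXD73, BXD87, BXD89, BXD100, BXD103 and DBA/2J. Fisher's test takes the 80 arrays as independent and ignores the pairing by strain, and the cut was set at the gap in these same values.

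A few genes separated the diets completely. In 447 of 38827 genes the change had the same direction in all 38 strains, 77 of them by at least 0.5 units, and so it had in 15 of 1766 receptor genes. In 22 genes (0 receptor genes) the arrays of both diets did not overlap at all. A free shuffle of the 76 arrays, which ignores the pairing by strain, gives a share of 2.9e-22. Neither count separates an effect of diet from a difference between arrays that follows diet. Mir200c lay between 5.65 and 6.73 on chow and between 7.39 and 8.38 on high fat, and Mir543 between 5.46 and 6.35 and between 6.56 and 7.54. Agr3, at levels below the array mean, lay between 4.97 and 5.38 and between 5.45 and 5.93. Mir543 and Agr3 were chosen after their values were seen.

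The other counts were compared with random regroupings. Chance is not excluded for the number of gene lists called by camera, because 40 of 100 assignments of diet within strains gave 15 lists or more, the real one included (highest other 28). Chance is excluded for the strain effect, where 1 of 100 pairings of high fat with chow arrays, the real one, gave 4035 genes (highest other 180). For the parents' contrast 1 of 100 drawn pairs of strains, the real one, gave 4539 genes (highest other 4528), but pairs outside the draw gave more. Of all 703 pairs 4 reached the real count, all of them C57BL/6J against another strain (up to 7241 genes, against BXD65), so the count follows the C57BL/6J arrays and is not specific to the parents.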
